A study of Homo sapiens with 6 samples.

How the data were processed

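The series holds 6 RNA-seq libraries of HSC-3 cells, 3 of normal gravity and 3 of simulated microgravity, grouped by the sample titles. The titles call the libraries biological replicates. How separate the cultures were is not described further, so p-values measure the spread between these libraries, part of which may be technical. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with a VAHTS Universal kit and paired-end reads were sequenced on Illumina instruments. Both NovaSeq and HiSeq are named in the labels. The authors deposited whole-number read counts per gene, not normalized, in a single table for the whole series. Per the submitters' processing notes, fastp, HISAT, HTSeq, R 3.2.0, DESeq2 and the hg38 build were used, with no roles or order given. The annotation release, the strand setting, the way messenger RNA was selected and the time in culture are not given in the sources used here. Columns of the count table carry a short group name and a number. The name of the rotary culture group is given in the treatment protocol, and the other name was taken as normal gravity because the series has no further group.

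The table has 22941 genes, 16322 protein-coding and 6619 non-coding, with no duplicated or unnamed rows and no gene at 0 in all libraries. Genes with too few counts were removed with filterByExpr of edgeR (minimum count 10), which left 14736. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood F-test (edgeR 4.0.16, robust, R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are approximate, taken as the size of the change divided by the square root of F. CPM values use the TMM-scaled library sizes. A group with 0 counts was set to a floor of 3 counts over the group, 0.0264 CPM in normal gravity and 0.0282 CPM in simulated microgravity, and a group with 1 to 3 counts was given an exact 95% binomial interval of the ratio. Reads carry no molecular identifiers, so these intervals and floors cover counting error only. Bootstrap intervals of medians, given further below, resample genes and not libraries, so they do not measure the spread between libraries. Within groups, chi-square per degree of freedom between libraries was between 17.9 and 142, so no pair of libraries agreed within sampling noise.

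A set of 30 gene lists was fixed before the data were examined, as were the rule for named genes, the tests and the main alternatives. The lists cover the mechanosensitive channels, calcium, autophagy, lysosome, cell cycle, differentiation, adhesion, metabolism, stress, signalling and other cell type groups reported below. Of their entries 1075 were matched by symbol and 33 through an older symbol, and 10 were not matched and not analysed here. The match of 1 mitochondrial gene, COX2, was corrected after the first result of its list had been seen, and both results are given. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 30 lists. Each was also tested with an estimated correlation and with fry. The estimated correlation called none of the 30 lists, and its lowest adjusted p, 0.559, was shared by many of them. Enrichment in the deposited KEGG, GO, WikiPathways and Reactome annotation used hypergeometric tests of higher and lower genes apart. The background was all tested genes that carry a term of that source, terms had 10 to 300 tested members, and p-values were adjusted over the terms of a source. Coordinates are those of RefSeq GRCh38.p14, a patch release of the build in the submitters' notes.

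The genes named are PIEZO1, SQSTM1, MAP1LC3B and BECN1, the 6 that rose most and the 6 that fell most, and for each list the members with the smallest adjusted p. The largest changes were taken among genes with an adjusted p under 0.05, a symbol that is not a clone or locus identifier (numbered LOC and LINC names, open reading frames and antisense or divergent transcripts were counted as such), at least 5 CPM in the higher group and no overlap between groups. From each list came 2 members, 1 per direction where members went both ways, and 3 from the channel, calcium and autophagy core lists. From each annotation term came the 2 members with the smallest adjusted p. Other genes are said to have been chosen after their values were seen.

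The gene and list tests were tested on simulated counts drawn from the means and dispersions of these libraries, over 14489 genes. They recovered 71 of 100 genes changed 2-fold and 89 of 100 changed 4-fold, with 9 false calls. A raised list was called and none of 20 unchanged lists was. The simulated genes were drawn independently and few of them were changed. Correlation within lists and scaling under a shift as wide as in the data were therefore not tested. Alternatives were DESeq2 size factors, library size only, no filter and a CPM filter, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom, a replicate block, each library left out, mitochondrial transcripts left out, and a correction for transcript length and GC content. Length and GC were taken from GENCODE transcripts and were found for 93.3% of tested genes. Figures were drawn with matplotlib 3.10.9.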

Results

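RNA was sequenced from HSC-3, an established human cell line from a squamous cell carcinoma of the oral cavity. The cells were grown under normal gravity or in a Rotary Cell Culture System, a rotating vessel used to simulate microgravity. Each condition had 3 biological replicate libraries. Total counts over genes were 37980774, 37276166 and 38861233 in the normal gravity libraries and 35401989, 34264008 and 36317678 in the simulated microgravity libraries. The series has 1 comparison, which asks how culture in simulated microgravity alters gene expression in these cells, and its title directs attention to PIEZO1, calcium and autophagy. Values below are normalised read counts (CPM, scaled by library size), as mean ± SD with n = 3, and log2 fold changes are simulated microgravity minus normal gravity. Rises and falls are therefore relative to the other transcripts of a library, and a change in total RNA per cell would not be seen.

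Cells in simulated microgravity had far higher transcripts of the cornified envelope, the protein shell of differentiated keratinocytes, and far lower transcripts of cell division. SPRR3, a cornified envelope precursor, was at 0.413 ± 0.165 CPM in normal gravity and 300.3 ± 13.9 CPM in simulated microgravity (log2 fold change 9.49, SE 0.23). PTTG1, the securin that restrains separase until anaphase, fell from 92.9 ± 8.18 to 7.30 ± 0.44 CPM (log2 fold change -3.67, SE 0.12). SQSTM1, the autophagy receptor p62, rose from 344 ± 43.6 to 1777 ± 148 CPM (log2 fold change 2.37, SE 0.15). The ion channel gene PIEZO1 rose from 115 ± 19.8 to 189 ± 26.2 CPM. Of 14736 genes tested, 8482 changed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 4157 higher and 4325 lower, and 4497 of them changed at least 2-fold. Changes of at least 8-fold were found for 703 genes that rose and 421 that fell. The first principal component, with 84.7% of the variance, separated the groups, and the second, with 7.59%, set normal gravity replicate 3 (-55.9) apart from replicates 1 (17.6) and 2 (36.3).

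**Figure D1:**
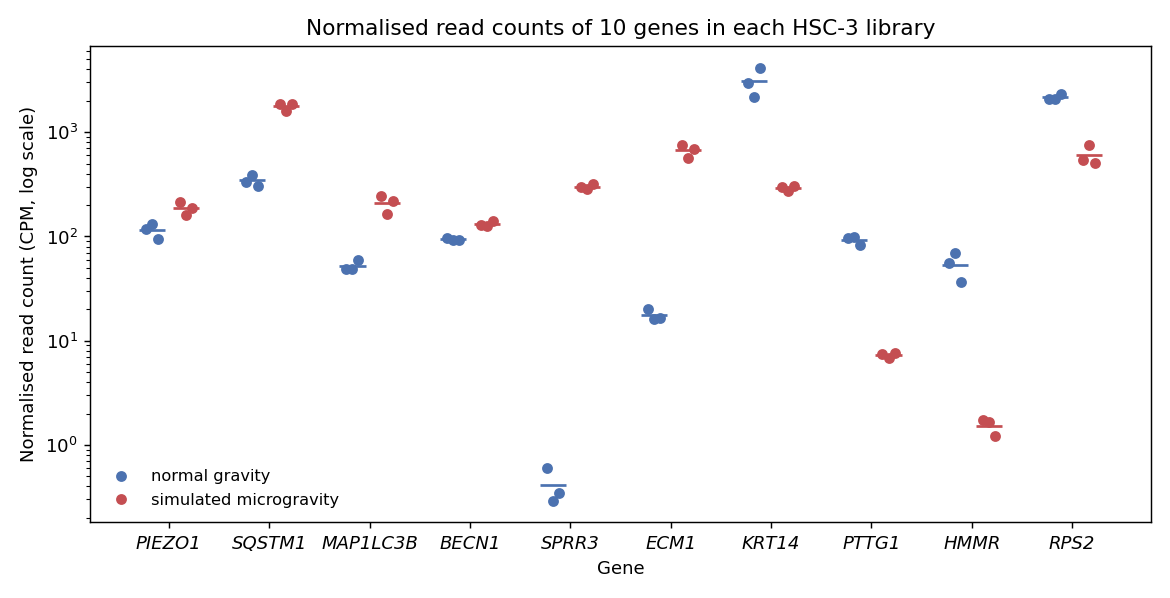
Normalised read counts (CPM, log axis) of 10 genes in each library. Points are single libraries, 3 per group, and horizontal lines are group means. SPRR3 lay between 0.293 and 0.602 CPM in normal gravity and between 287.8 and 315.2 CPM in simulated microgravity, while PIEZO1 lay between 93.8 and 132.8 CPM and between 162.4 and 214.8 CPM.

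Ranked by fitted log2 fold change, and leaving out names that are locus identifiers, 4 of the first 6 genes that rose belonged to the late cornified envelope family on chromosome 1. The identifiers left out above the last of these were LINC00302, a non-coding RNA with a fitted change of 11.25, and LOC122526777, with 0 counts in normal gravity. LCE1E had 0 counts in the normal gravity libraries and 24.5 ± 8.01 CPM in simulated microgravity, at least 927-fold higher against a floor of 3 counts over the group. LCE1A had 1 count in normal gravity and 85.8 ± 35.9 CPM in simulated microgravity, a ratio of 9710 with a 95% counting interval from 1740 to 383000. LCE3A also had 1 count, with a ratio of 2240 (401 to 88300), and LCE2C rose from 0.0619 ± 0.0615 to 109 ± 42.2 CPM. Members of this family are near-identical copies, so the split of reads among them is uncertain. PTPN5, a tyrosine phosphatase, had 0 counts in normal gravity and was at least 302-fold higher. The places of LCE1E and PTPN5 in the ranking rest on fitted values of 12.81 and 11.19, while their bounds of 9.86 and 8.24 lie below the 10.66 of LCE3A, the last of these 6 genes. TRIM63, a ubiquitin ligase best known from muscle, had 3 counts in normal gravity and 67.5 ± 21.3 CPM in simulated microgravity, a ratio of 2560 (876 to 12400). The largest falls were in RNF165, CXCL14, SEMA6B, C1QL1, MND1 and TROAP. RNF165 fell from 5.35 ± 2.72 CPM to 3 counts over the group, a ratio of 190 (64.7 to 924). SEMA6B, a semaphorin, fell from 15.5 ± 2.69 to 0.179 ± 0.062 CPM, and C1QL1 from 8.86 ± 2.83 to 0.112 ± 0.085 CPM. MND1, a meiotic recombination factor, had a log2 fold change of -6.09 (SE 0.58) and TROAP, a spindle-associated protein, of -5.97 (SE 0.39). The chemokine CXCL14 was at 4.16, 1.60 and 34.5 CPM in the normal gravity libraries and 0.124 ± 0.120 CPM in simulated microgravity (adjusted p = 0.0047). Its call was lost with limma-voom (adjusted p = 0.0903) and without the low-count filter (adjusted p = 0.0549).

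PIEZO1, a mechanically gated cation channel (chromosome 16, 88715338 to 88785220, RefSeq GRCh38.p14), rose by a log2 fold change of 0.71 (SE 0.16, adjusted p = 0.00445) and was higher in each simulated microgravity library than in each normal gravity library. Of 23 tested mechanosensitive and calcium entry channels, 10 rose, 7 fell and 6 did not pass, with the same counts adjusted over the list alone. TMEM63A, a stretch-activated channel, rose from 30.7 ± 0.41 to 130.5 ± 8.02 CPM. TRPV3, a warmth-sensing channel of keratinocytes, had 3 counts in normal gravity and 18.3 ± 4.80 CPM in simulated microgravity, a ratio of 689 (236 to 3350). PKD2, a calcium-permeable channel of cilia and endoplasmic reticulum, fell from 25.4 ± 4.04 to 9.27 ± 2.60 CPM. The list did not stand apart from other genes (camera, adjusted p = 0.25). The fry test, which asks only whether the members move one way on balance, gave an adjusted p of 0.00213.

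Genes of calcium stores, pumps and calcium signalling went both ways: of 44 tested, 11 rose, 12 fell and 21 did not pass, with the same counts adjusted over the list alone. SLC8B1, the mitochondrial sodium-calcium exchanger, rose from 20.1 ± 0.87 to 62.4 ± 9.73 CPM. SLC8A1, the plasma membrane sodium-calcium exchanger, fell from 7.85 ± 3.38 to 0.591 ± 0.17 CPM. PLCG1, the phospholipase that releases the calcium-mobilising messenger IP3, fell from 122 ± 8.0 to 50.2 ± 2.41 CPM. The list was not called (camera, adjusted p = 0.79). Its median log2 fold change was 0.028 while its mean was -0.165 and the test pointed down. The sign of the median rests on single libraries: it was -0.0801 without normal gravity replicate 3, -0.0428 without normal gravity replicate 2 and -0.0342 without simulated microgravity replicate 1, against 0.0515 and 0.0554 without simulated microgravity replicates 2 and 3.

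The autophagy core machinery rose as a group: of 39 tested genes, 27 rose, 3 fell and 9 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.80 (camera, adjusted p = 4.49e-05; adjusted p = 0.559 with an estimated correlation). MAP1LC3B, the LC3 protein that coats autophagosomes, rose from 52.4 ± 6.65 to 209 ± 41.4 CPM (log2 fold change 1.99, SE 0.17, adjusted p = 3.63e-05). BECN1, a subunit of the lipid kinase that starts autophagosomes, rose from 93.8 ± 2.96 to 131.5 ± 6.82 CPM (log2 fold change 0.49, SE 0.09, adjusted p = 0.00214). EPG5, a tether for fusion with lysosomes, and ATG2A, a lipid transfer protein, had log2 fold changes of 2.03 (SE 0.15) and 1.90 (SE 0.15). The genes that fell were ULK2, an initiating kinase, at -2.19 (SE 0.29), and ATG4C and ATG10, which were named after their values were seen. Reads of MAP1LC3B and of its copy MAP1LC3B2 may be split uncertainly.

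Autophagy receptors were not called as a group (camera, adjusted p = 0.171), with 9 of 18 higher and 3 lower. SQSTM1 rose 5.16-fold, whereas BNIP3, a mitophagy receptor induced by hypoxia, fell from 146 ± 8.30 to 55.0 ± 3.65 CPM. Lysosomal genes had 23 of 45 higher and 8 lower (adjusted p = 0.0968). NEU1, a lysosomal sialidase, rose to 286 ± 50.1 CPM from 61.1 ± 3.46, and the protease gene CTSZ fell to 31.9 ± 5.20 from 116 ± 22.1 CPM. In the mTORC1 and AMPK list, 16 of 38 rose and 7 fell (adjusted p = 0.155). FLCN, a regulator of lysosomal mTORC1 signalling, had a log2 fold change of 1.86 (SE 0.13), and PRKAB2, an AMPK subunit, of -1.35 (SE 0.19). Adjusted over the list alone, the counts of these 3 lists were the same.

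Cell division genes fell almost throughout. In the G2/M and mitosis list 47 of 48 genes fell and none rose, with a median log2 fold change of -4.71 (camera, adjusted p = 2.87e-18; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone, 48 fell. HMMR, a spindle assembly factor, fell from 53.8 ± 16.5 to 1.53 ± 0.28 CPM. In the G1/S and DNA replication list 46 of 51 fell and 1 rose, with a median of -2.32 (camera, adjusted p = 7.75e-10; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone, 47 fell. The gene that rose was CCND1, cyclin D1, from 209 ± 77.0 to 653 ± 31.0 CPM, while CCND2, cyclin D2, fell from 71.95 ± 5.60 to 14.4 ± 1.08 CPM. Within normal gravity, replicate 3 had lower values of both lists than the mean of replicates 1 and 2, by a median of -1.37 for G1/S and -1.11 for G2/M.

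Replication-dependent histone genes moved opposite to the cell cycle lists, with 12 of 15 higher, 1 lower and a median log2 fold change of 2.64 (camera, adjusted p = 5.72e-04; adjusted p = 0.559 with an estimated correlation). H1-3 rose from 0.0442 ± 0.0308 to 2.68 ± 0.47 CPM, and H3C2 fell from 0.388 ± 0.044 CPM to 1 count over the group, a ratio of 41.3 (7.04 to 1670). Counts were the same adjusted over the list alone, and reads shared among histone copies make single members uncertain. In normal gravity replicate 3 the list lay 0.98 above the other 2 libraries. Non-coding genes took 1.07%, 0.999% and 1.22% of counts in normal gravity replicates 1, 2 and 3, and 1.86%, 1.63% and 1.74% in those of simulated microgravity. How messenger RNA was selected is not given in the sources used here. A change in which RNA was captured therefore cannot be told apart from a rise in histone expression. Of the p53 targets and cell cycle inhibitors, 14 of 29 rose and 9 fell (camera, adjusted p = 0.245). PLK3, a stress-responsive kinase, rose from 4.83 ± 2.26 to 114 ± 21.1 CPM and CCNG1, cyclin G1, fell from 48.7 ± 1.12 to 22.3 ± 2.50 CPM.

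Keratinocyte differentiation genes rose, with 41 of 47 higher, none lower and a median log2 fold change of 4.39 (camera, adjusted p = 1.45e-14; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone, 41 rose and 1 fell. Besides SPRR3, the gene with the next smallest adjusted p was ECM1, a secreted matrix protein of the epidermis, which rose from 17.5 ± 2.23 to 669 ± 91.2 CPM. In normal gravity replicate 3 the list lay 0.58 above the other 2 libraries, and replicate 2 was at -0.561 against its other 2. Epithelial adhesion and desmosome genes had 25 of 40 higher and 6 lower, with a median of 0.96 (camera, adjusted p = 0.00105; adjusted p = 0.559 with an estimated correlation), and 25 higher and 8 lower adjusted over the list alone. CLDN4, a tight junction claudin, rose from 7.36 ± 1.27 to 527 ± 138 CPM. KRT14, the keratin of basal cells, fell from 3106 ± 1008 to 292 ± 14.95 CPM.

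Genes of the epithelial-mesenchymal transition fell on balance, with 18 of 34 lower and 7 higher and a median log2 fold change of -1.13 (camera, adjusted p = 0.0218; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone, 19 fell and 7 rose. LOXL2, a collagen-crosslinking oxidase, fell from 276 ± 16.1 to 42.5 ± 4.50 CPM, and PLAUR, the urokinase receptor, rose from 7.97 ± 1.85 to 70.2 ± 8.79 CPM. Matrix proteases and their inhibitors went both ways, 11 higher and 9 lower of 30 (camera, adjusted p = 0.482), and PLAT, tissue plasminogen activator, fell from 19.3 ± 4.01 to 3.91 ± 0.77 CPM. Integrin and focal adhesion genes had 8 higher and 16 lower of 39 (adjusted p = 0.365). ITGA2, the collagen receptor subunit, rose from 91.9 ± 11.7 to 1113 ± 254 CPM, and CAV1, the coat protein of caveolae, fell from 1552 ± 474 to 80.4 ± 9.78 CPM. Among actomyosin and SRF targets 8 of 38 rose and 18 fell (adjusted p = 0.133, and 0.0422 without normal gravity replicate 3), with 10 and 19 adjusted over the list alone. TPM2, a tropomyosin, had a log2 fold change of -3.60 (SE 0.16) and PDLIM5, a Z-disc adaptor, of 1.73 (SE 0.12). YAP/TAZ targets had 12 of 34 higher and 15 lower (adjusted p = 0.279), 17 lower adjusted over the list alone, with KRT34 at 4.68 (SE 0.38) and FJX1 at -2.51 (SE 0.15).

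Transcripts of protein synthesis and respiration also fell. All 52 cytosolic ribosomal protein genes in the list fell, also adjusted over the list alone, with a median log2 fold change of -0.995 (camera, adjusted p = 2.84e-13; adjusted p = 0.559 with an estimated correlation). RPS2 fell from 2162 ± 151 to 602 ± 135 CPM and RPS3 from 803 ± 66.2 to 301 ± 56.1 CPM. These genes have many processed pseudogenes, so their read assignment is uncertain. Of 50 nuclear-encoded respiratory chain genes 44 fell and none rose, with a median of -0.60 (camera, adjusted p = 4.41e-09; adjusted p = 0.559 with an estimated correlation), and 45 fell adjusted over the list alone. The ATP synthase subunit genes ATP5MC3 and ATP5MC1 had log2 fold changes of -1.21 (SE 0.09) and -1.49 (SE 0.12).

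Mitochondrially encoded transcripts took 10.7% ± 1.31 of counts in normal gravity and 8.02% ± 0.54 in simulated microgravity. Of 13 tested, 6 fell and none rose, with a median log2 fold change of -0.44, and 5 fell adjusted over the list alone. COX3 fell from 13570 ± 2019 to 6095 ± 598 CPM and ND6 from 378 ± 79.8 to 122 ± 1.11 CPM. The call of this list was marginal (camera, adjusted p = 0.0384; adjusted p = 0.623 with an estimated correlation). It rests on a correction made after the first result was seen: the first run had not matched COX2 and gave an adjusted p of 0.0526. It was also lost without normal gravity replicate 3 (0.108), simulated microgravity replicate 2 (0.0837) or replicate 3 (0.0648). With a correction for transcript length and GC content the call also ended (adjusted p = 0.156), as the median moved from -0.442 (95% bootstrap interval -0.535 to -0.162) to -0.225 (-0.509 to 0.0829), nearer to 0 and with a wider interval. It was not called with a filter of CPM above 1 in 3 libraries (0.0572) or with fry (0.0513). ND6 lies on the opposite strand to most mitochondrial genes, and a strand setting of the counting is not given in the sources used here.

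Hypoxia and glycolysis genes fell, with 27 of 42 lower and 4 higher and a median log2 fold change of -0.88 (camera, adjusted p = 5.07e-04; adjusted p = 0.559 with an estimated correlation). Adjusted over the list alone, 28 fell. BNIP3 was the gene with the smallest adjusted p among those that fell, and ANGPTL4, a secreted lipase inhibitor, rose from 2.38 ± 1.28 to 42.1 ± 7.11 CPM. Cholesterol and fatty acid synthesis genes were not called, with 7 of 35 higher and 10 lower (camera, adjusted p = 0.485). LPIN1, a phosphatidate phosphatase, had a log2 fold change of 2.95 (SE 0.22) and FADS1, a fatty acid desaturase, of -2.27 (SE 0.22).

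Immediate early genes and feedback regulators of MAPK signalling rose, with 21 of 39 higher and 3 lower and a median log2 fold change of 1.06 (camera, adjusted p = 0.00935; adjusted p = 0.559 with an estimated correlation). HBEGF, a ligand of the EGF receptor, rose from 13.5 ± 5.56 to 213 ± 10.9 CPM. The genes that fell were the growth-associated transcription factor genes MYC, from 404 ± 68.8 to 86.4 ± 13.2 CPM, FOS and EGR1, the last 2 named after their values were seen. Counts were the same adjusted over the list alone. FOS was at 691 CPM in normal gravity replicate 3 and at 149 and 119 CPM in replicates 1 and 2. Apoptosis regulators had 14 of 29 higher and 2 lower, also adjusted over the list alone (camera, adjusted p = 0.021; adjusted p = 0.559 with an estimated correlation). XIAP, a caspase inhibitor, rose 2.03-fold and CYCS, cytochrome c, fell from 255 ± 65.5 to 157 ± 7.79 CPM. The call of the list was lost without simulated microgravity replicate 3 (adjusted p = 0.0648).

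Stress and immune lists were not called by camera. The unfolded protein and integrated stress response had 20 of 39 higher and 9 lower (adjusted p = 0.0625, but 0.0485 with limma-voom, 0.0368 without normal gravity replicate 2 and 0.0478 without simulated microgravity replicate 2), with 21 higher adjusted over the list alone. ERN1, the stress sensor IRE1, had a log2 fold change of 2.24 (SE 0.14) and PHGDH, an enzyme of serine synthesis, of -2.58 (SE 0.12). Heat shock genes had 8 of 24 higher and 6 lower (adjusted p = 0.416), with HSPA1B at 1.47 (SE 0.12), whose reads are shared with a near-identical copy, and HSPA4L at -2.51 (SE 0.26). The oxidative stress and metallothionein list had 15 of 33 higher and 10 lower (adjusted p = 0.31), with FTH1, the ferritin heavy chain, at 1.78 (SE 0.14) and MT1E at -2.72 (SE 0.17). Interferon response genes had 10 of 42 higher and 17 lower (adjusted p = 0.309), 18 lower adjusted over the list alone, with CXCL11 at 3.67 (SE 0.43) and IFIT1 at -2.63 (SE 0.24). Inflammatory cytokines and NF-kB targets had 11 higher and 11 lower of 37 (adjusted p = 0.621), 12 lower adjusted over the list alone. LCN2, an iron-sequestering protein, rose from 30.9 ± 5.89 to 1682 ± 353 CPM, and the chemokine CXCL2 fell from 16.2 ± 5.05 to 3.48 ± 0.32 CPM. Of 12 tested markers of fibroblasts, endothelium and immune cells 5 rose and none fell (adjusted p = 0.161, and 0.0488 without normal gravity replicate 3). CD14 rose from 28.7 ± 2.00 to 89.0 ± 16.7 CPM and CD68 from 93.6 ± 15.1 to 188 ± 13.2 CPM.

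**Figure D2:**
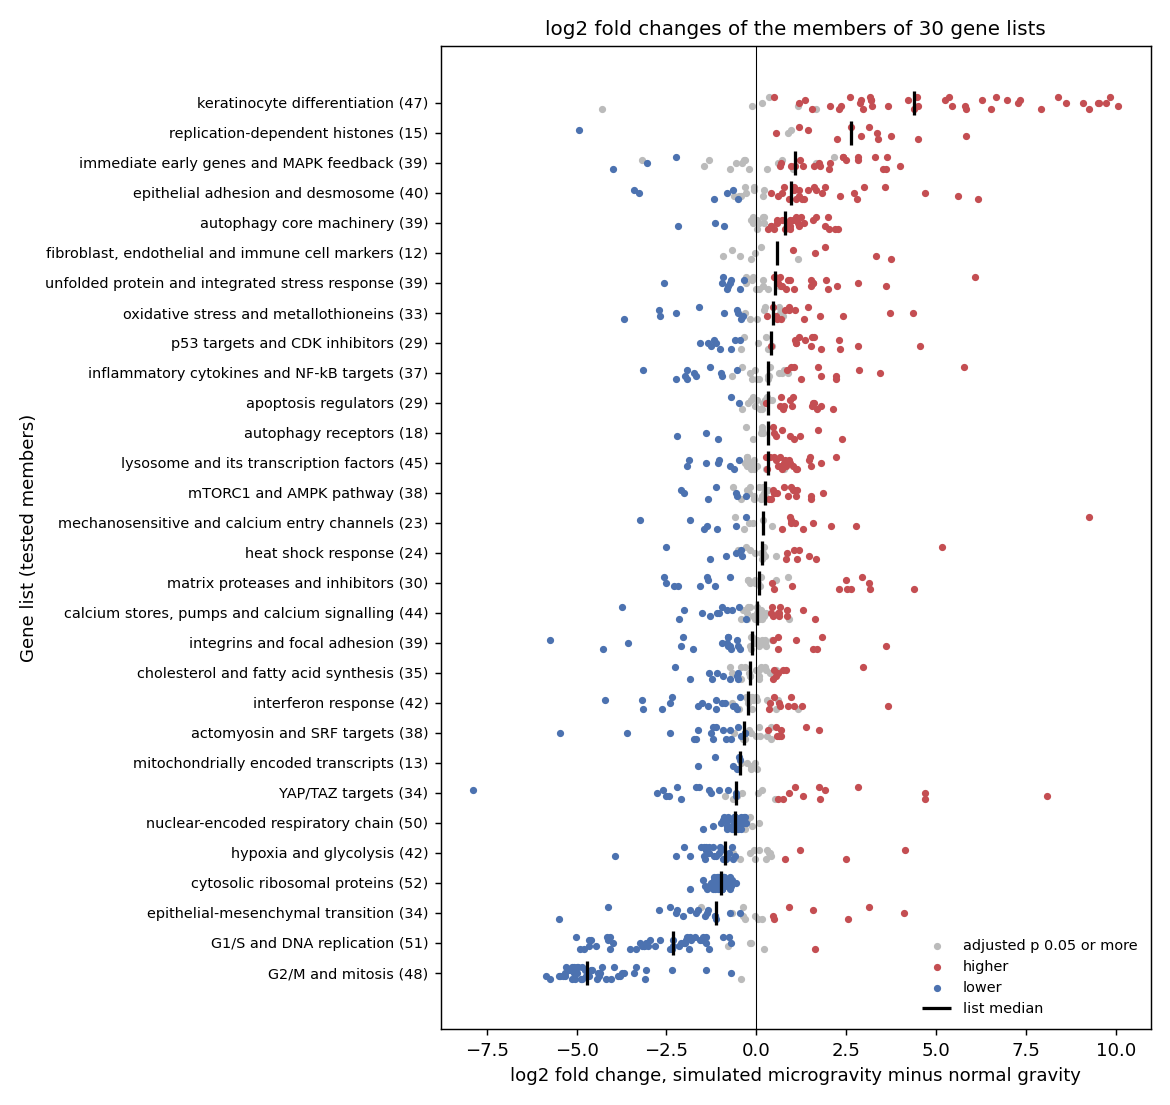
Fitted log2 fold changes of the tested members of 30 gene lists, ordered by list median. Each point is a gene (red higher, blue lower, grey with an adjusted p of 0.05 or more), black bars are list medians and numbers in brackets are tested members. The keratinocyte differentiation list has the highest median, 4.39, and the G2/M and mitosis list the lowest, -4.71.

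In the pathway annotation deposited with the counts, genes that rose were enriched in the Reactome term for keratinization (70 of 97 tested genes, adjusted p = 1.45e-16), with SPRR3 and SPRR2A at the smallest adjusted p. They were also enriched in the KEGG terms for autophagy (63 of 128, adjusted p = 1.92e-05; ATG9B and SQSTM1), endocytosis (100 of 226, adjusted p = 1.01e-05; RAB11FIP1 and PARD6B), tight junction (58 of 134, adjusted p = 0.00451; CLDN4 and CGN) and circadian rhythm (18 of 30, adjusted p = 0.0101; NPAS2 and CRY1). Genes that fell were enriched in the KEGG terms for the ribosome (108 of 129, adjusted p = 9.65e-30; RPSA and RPS2), DNA replication (30 of 35, adjusted p = 2.99e-08; PRIM1 and RFC3) and oxidative phosphorylation (73 of 122, adjusted p = 1.85e-07; ATP5MC3 and ATP5MC1). When genes also had to change at least 2-fold, keratinization (adjusted p = 9.26e-32), the ribosome (3.34e-05) and DNA replication (3.02e-10) were still called. The calls of the KEGG terms for autophagy (0.138), tight junction (0.138), circadian rhythm (0.81), endocytosis (1) and oxidative phosphorylation (1) were lost. GO terms for parts of autophagy were still called at 2-fold, among them autophagosome assembly (21 of 58, adjusted p = 0.00133; ATG9B and TCIRG1) and phagophore assembly site (15 of 28, adjusted p = 0.000103; ATG9B and SQSTM1), whereas the GO terms for autophagy (0.992) and macroautophagy (0.0729) were not. The GO term for the bicellular tight junction was also called at 2-fold (32 of 98, adjusted p = 0.000105; CLDN4 and CGN). Terms overlap, and the hypergeometric test treats genes as independent.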

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

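The alternatives were fixed before the data were examined, except the removal of SPRR and LCE genes from the keratinocyte list and the mitochondrial list with COX2 unmatched, which were chosen after the data were seen. The number of changed genes lay between 6938 and 9555 over all alternatives, within 1.5 times the reported 8482, and both ends came from leaving out a library (simulated microgravity replicate 1 and normal gravity replicate 3). With the DESeq2 Wald test 8269 of the 8482 genes were called again, and with limma-voom 8346, all in the same direction. PIEZO1 stayed higher with an adjusted p under 0.05 under each alternative, with log2 fold changes from 0.58 (without normal gravity replicate 3) to 0.83 (without normal gravity replicate 2). No named gene and no called list changed direction, and CXCL14 was the only named gene to lose its call. Each of the 13 lists that camera had called lost its call with an estimated correlation. That setting called none of the 30 lists. Its lowest adjusted p, 0.559, was shared by lists as unlike as G2/M (median -4.71) and mTORC1 and AMPK (0.229, not called by camera). The loss therefore does not set weak lists apart from strong ones. No other alternative ended the call of the autophagy core list (adjusted p = 0.559 with the estimated correlation), and the cause was not tested. The channel list was called only with fry (adjusted p = 0.00213), which does not compare it with other genes and called 10 lists that camera had not. Enriched annotation terms numbered 609, and 355 when genes also had to change at least 2-fold, where fewer genes count as changed. The KEGG terms for autophagy, endocytosis, tight junction, circadian rhythm and oxidative phosphorylation were among those lost, while GO terms for autophagosome assembly (0.00133), phagophore assembly site (0.000103) and bicellular tight junction (0.000105) were called at 2-fold. The unfolded protein list was called with limma-voom (0.0485). The mitochondrial list also lost its call with the CPM filter (0.0572), with the length and GC correction (0.156) and with fry (0.0513).

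Equal replicate numbers did not pair libraries: deviations of same-numbered libraries from their group means correlated at 0.049, -0.044 and -0.017, and not every library correlated best with its own number. With the replicate number as a block 7860 genes were called, 3875 higher and 3985 lower, and no call of a list or named gene changed.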

Other observations

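Several of the genes that rose most lie in the epidermal differentiation complex, a region chosen because of them after the values were seen, so its counts are given without a test. On chromosome 1 from S100A10 to S100A1 (151982915 to 153632039, RefSeq GRCh38.p14), 46 of 56 tested genes rose and 3 fell, against 465 of 1516 that rose on the rest of the chromosome. Outside the LCE and SPRR families 19 of 29 rose. Inside the region IVL, involucrin, rose from 0.228 ± 0.196 to 55.6 ± 10.2 CPM, while S100A10 at its edge was at 413 and 403 CPM and S100A2, a basal-cell protein, fell from 762 to 336 CPM.

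The following genes were chosen after their values were seen. ATG9B, a relative of the autophagy lipid scramblase ATG9A that was not in the autophagy list, rose from 0.662 ± 0.188 to 492 ± 68.9 CPM. The membrane mucin genes MUC16 and MUC4 rose from 0.556 ± 0.229 to 190 ± 19.2 CPM and from 0.239 ± 0.212 to 53.8 ± 1.89 CPM. The basal keratin gene KRT5 fell from 9712 ± 2675 to 1011 ± 245 CPM, TP63, the transcription factor of basal cells, from 323.5 ± 70.7 to 93.8 ± 24.7 CPM, and the proliferation marker MKI67 from 518 ± 256 to 11.5 ± 2.39 CPM. CDKN1A, the inhibitor p21, rose from 124 ± 32.9 to 434 ± 42.8 CPM.

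The tests in this part were chosen after the result was seen, except those of length and GC content and of other splits of the libraries. Of the 10 splits of the 6 libraries into 3 and 3, only the real split, 1 of 10, gave as many as 8482 genes. The highest of the others gave 0 with edgeR and 0 with limma-voom, and 238 at an unadjusted p under 0.05. Each of the other splits mixes both conditions on each side, so the large difference between conditions counts there as spread within groups and leaves few calls. With 10 splits the share also cannot fall under 0.1, so the splits decide nothing about chance.

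For the rise of cornified envelope and keratinocyte differentiation genes, reads shared between near-identical copies were weighed first. The 40 list members outside the LCE and SPRR families had a median log2 fold change of 3.2 (95% bootstrap interval 2.74 to 4.87), which argues against shared reads as the whole cause of the list's rise. They are most of the 47 tested members, and they do not bear on the LCE and SPRR genes themselves. Every tested LCE and SPRR gene of the chromosome 1 region rose at an adjusted p under 0.05 (edgeR). Their fitted log2 fold changes ran from 5.20 (SPRR4) to 12.81 (LCE1E), and LCE3D rose from 2.57 to 2185 CPM. Sharing moves reads between copies, so these values argue against it as the cause of the families' rise. The share of each copy stays uncertain. A minority of other, differentiated cells mixed into unchanged cultures would lower cell division genes by at most a log2 fold change of 1. The G2/M list, however, had a median of -4.71 (interval over genes -4.97 to -4.37). In single normal gravity libraries this list lay between -1.11 and 0.799 against the rest of the group, a spread that the interval leaves out. Most cells of the rotary cultures may therefore have left division, a hypothesis found and tested on the same data. Whether most of them or only some turned on a program of differentiation cannot be told from libraries of whole cultures. The labels state neither the time in culture nor whether the normal gravity cells were attached or in suspension, and cell density and aggregation were not measured here, so the part of these and that of gravity stay open.

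The fall of ribosomal protein and respiratory chain transcripts, which are short, was set against a trend of fold change with transcript length and GC content. After that trend was taken out, the ribosomal median was -0.872 (95% bootstrap interval -0.907 to -0.828) against -0.995 before, and the respiratory chain median -0.459 (-0.552 to -0.362) against -0.597. Most of each fall stayed, which argues against the trend as the whole cause. Reads shared with pseudogenes were not tested.

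Normal gravity replicate 3 had lower replication transcripts than the other 2 normal gravity libraries. RNA from simulated microgravity cells in that library would raise transcripts found almost only there, but 26 such transcripts (mean under 0.5 CPM in replicates 1 and 2, with replicate 3 not used to choose them, and at least 50 CPM in simulated microgravity) allowed a median share of 0.0289% (95% bootstrap interval -0.0388 to 0.0862), against 63.4% needed for the fall of 93 replication and mitosis genes. Lower depth is also argued against, since this library had the highest total count of its group, 38861233. A shared axis of less proliferation and more differentiation may link this library with the simulated microgravity group. Its list medians against the other 2 went both ways. Keratinocyte differentiation lay 0.583 higher, as it did in simulated microgravity. Replicate 2 was also apart on that list, at -0.561 against its other 2 libraries, so the shift is not particular to replicate 3. In replicate 3 cytosolic ribosomal proteins (0.158) and mitochondrially encoded transcripts (0.365) also lay higher, though both lists fell in simulated microgravity. Across 14637 genes outside the cell cycle lists, replicate 3 minus replicate 2 and simulated microgravity minus replicate 1 correlated at only r = 0.135 (rho = 0.154), between the bounds set for and against it, so this stays undecided.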
